A study of Danio rerio with 12 samples.

How the data were processed

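Gene expression was measured by RNA sequencing in livers of adult wild-type zebrafish of the TU strain. Per the labels' protocols, fish aged 4 months were kept for 28 days with bisphenol AF (BPAF), a fluorinated analogue of bisphenol A, at 10 µg/L, or with 0.0001% of the solvent dimethyl sulfoxide (DMSO) as control. No DMSO level was found in the labels for the exposed fish, so a difference in solvent cannot be told apart from BPAF. The water was at 28 °C with 14 h of light and 10 h of dark per day, RNA was isolated with TRIzol, and libraries were prepared with an Illumina TruSeq kit. The 12 libraries were placed in 4 groups of 3 (male DMSO, male BPAF, female DMSO, female BPAF) by the sex, treatment and replicate number in their labels. The labels do not say whether the 3 libraries of a group came from separate animals or pools, so all p-values measure only the spread between these samples, which may be technical.

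The deposited table lists 32520 zebrafish genes with 1 value per library, which were taken as TPM, transcript abundances made by the authors relative to gene length and library total. The unit was inferred, since the file header names none: the values have 2 decimals, the listed genes of each library sum to between 978504.61 and 992375.41, and RSEM is among the tools named. HISAT2 2.1.0, Cufflinks and RSEM are named in the submitters' processing notes without a role or order, and the genome build and annotation version are not given in the sources used here. The 4 columns of group means in the table are the authors' means and were not used as replicates. There were 0 columns that could not be assigned to a sample or a group. Gene symbols are those of the deposited table, with 80 genes listed without a symbol and 561 symbols shared by several identifiers. Of the 32520 identifiers, 29201 were also found in a separate gene name table, and names from the GRCz12tu assembly were used only to match older symbols. No coordinates are given because no build could be tied to the table.

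TPM keep no sequencing depth, so the depth of each library is unknown, and neither counting intervals nor detection floors were computed. Because every library is scaled to the same total, a few very abundant genes in one group lower the values of the remaining genes in that group. A gene at 0 is described as listed at 0, and no fold change is given against a group at 0. Near-identical gene copies share reads, and how the authors split these is not given in the sources used here, so values of single vitellogenin, zona pellucida, globin and ribosomal RNA copies are uncertain.

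Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior, in a single model with a mean per group over all 12 libraries and 8 residual degrees of freedom. Genes were tested where TPM reached 1 in at least 3 libraries, which left 11389 of the 32520 genes, and 7000 genes were at 0 in all libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. Fold changes are on the log2(TPM + 1) scale and therefore understate the change of low genes. The contrasts were BPAF against DMSO in males and in females, the difference between these responses (female minus male, the interaction), females against males among the DMSO controls, and females against males averaged over treatment. The tests, the filter, the threshold, the rule for named genes and all gene lists were chosen before the data were examined, with a count model planned if the values had been counts and the limma model if they were TPM. Single values compared between groups were tested with 2-sided exact permutation tests.

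The 46 gene lists comprised 31 metabolic, stress, immune and hormone programmes and 15 sets of markers of cell types that a dissected liver could hold, and 43 lists had at least 5 tested members. Some lists share members, and 10 of the 17 hepatocyte markers were also in another list. Each list was compared with all other tested genes by camera of limma with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same lists were tested by camera with a correlation estimated from the data and by fry, which asks whether the members move on balance in one direction. Members were also tested with p-values adjusted over the list alone.

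Genes were named by a fixed rule. In each treatment contrast it takes up to 10 genes per direction that pass the threshold with an absolute log2 fold change of at least 1, do not overlap between groups and have a descriptive symbol. Where fewer than 5 qualify in a direction, it takes the 5 with the smallest p, which are then said not to pass. The rule further takes 5 genes per direction for the interaction and for females against males, a panel of 20 liver and estrogen-responsive genes whatever their result, and up to 4 members of each list that passed. The 6 genes that passed in males have clone-based symbols outside the rule and were named after their values were seen.

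The model was tested on simulated data in which known changes were added to about 200 genes. The noise was normal and drawn independently for each gene and library. Shifts of whole libraries, transcripts of other tissues and pairing were left out, so the shares and false calls may not hold for the real libraries. For males, 16.9% of genes changed by 1 on the log2 scale, 60.3% of those changed by 2 and 82.3% of those changed by 4 were recovered among 11701 tested genes, with 8 false calls. For females the shares were 15.2%, 58.5% and 75.0% among 11690 tested genes, with 5 false calls. For the interaction, changes of 1, 2 and 4 made in males only were recovered in 1.54%, 42.9% and 71.0% of genes, and those made in females only in 6.06%, 27.7% and 60.9%.

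Replicate numbers 1 to 3 recur in every group, and the labels do not say what they stand for. Deviations from the group means were correlated across genes at 0.327, 0.347 and 0.376 in the 3 pairs of male libraries with the same number, so the numbers were treated as pairing the male libraries, a pairing that comes from the data and not from the labels. The pairing is uncertain. The 3 values are tied to each other, because the deviations within a group of 3 sum to 0 for each gene. In addition, male DMSO 3 and female BPAF 1, of different sex and number, reached 0.356. For male DMSO 2 and female BPAF 2 the value was 0.292. The female pairs gave 0.226, 0.0526 and 0.104 and were not treated as paired. The planned model has no replicate block. The alternatives were a model without the trend, scaling by trimmed means computed in the manner of TMM on the TPM values, quantile normalization, no filter and a filter at 5 TPM, pseudocounts of 0.1 and 5, only the libraries of a comparison, the replicate number as a block over all libraries or within each sex, array quality weights, a fold change minimum, and each of the 12 libraries left out in turn. The block within each sex, the scaling of the list tests and of the sets of sex-biased genes, the estimated correlation for the latter, and set tests between the sexes were added after the data had been seen. For sex-biased genes chosen in the DMSO libraries, 100 draws with no change were simulated from the sex means plus whole-library residuals drawn with replacement within each sex, and again with same-numbered male libraries drawn together. Marker levels of same-numbered males were compared by exact sign changes of the 3 differences, also added then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.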

Results

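Liver expression was measured in 12 libraries of adult zebrafish, 3 each from control males, BPAF-exposed males, control females and BPAF-exposed females, to ask how the livers of the sexes differ in their response to 28 days at 10 µg/L BPAF. The listed genes summed to between 978504.61 and 992375.41 TPM per library, and the sequencing depth is unknown. Of 32520 listed genes, 11389 were tested. Genes at 1 TPM or more numbered 9108 to 12313 in the male libraries and 7007 to 9217 in the female libraries, with 12313 in male BPAF 1. The mean was 10300 ± 1080 in males and 7955 ± 748 in females (SD, n = 6 each, exact permutation test over 924 splits, p = 0.00433). Exposed males had 10960 ± 1170 and control males 9634 ± 459 such genes (SD, n = 3 each, exact permutation p = 0.1, the smallest that 20 splits allow). The number was higher in the exposed male of all 3 same-numbered pairs, by 2360, 356 and 1260. Exposed and control females had 7910 ± 1160 and 8000 ± 220 (exact permutation p = 0.9). Spearman correlations across genes were 0.772 to 0.876 between libraries of the same group, 0.787 to 0.888 between exposed and control libraries of the same sex and 0.618 to 0.81 between the sexes, and no library was a duplicate of another. The first principal component held 55.5% of the variance and placed all male libraries on one side and all female libraries on the other.

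**Figure D1:**
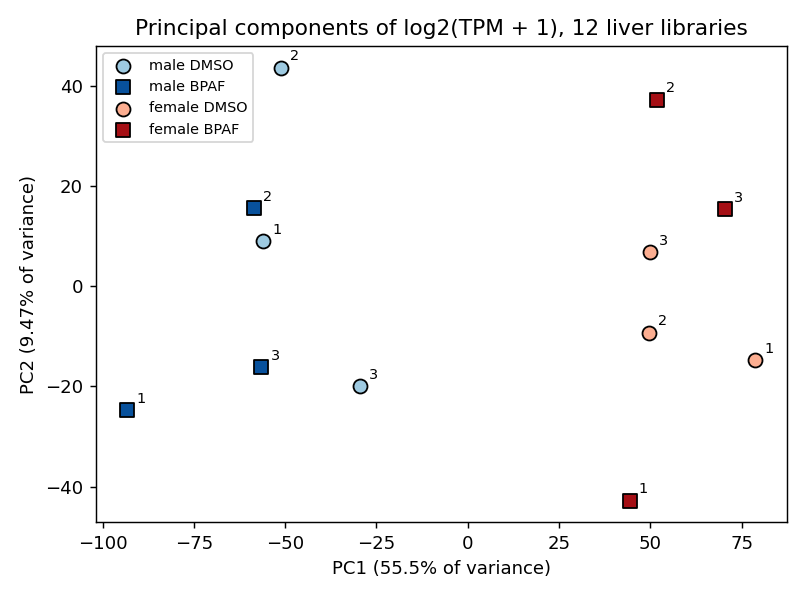
Scores of the 12 libraries on the first principal components of log2(TPM + 1), coloured by group and numbered by replicate. Component 1 (55.5% of variance) separates the sexes, and component 2 (9.47%) spreads the libraries of each group.

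The egg yolk precursor genes of the liver followed the sex labels in all 12 libraries. The 7 vitellogenin genes together took 22.7% ± 1.98 of all TPM in females and 0.00423% ± 0.00344 in males (SD, n = 6 each, exact permutation p = 0.00216, the smallest that 924 splits allow). In control livers, vtg1 stood at 137900 ± 11410 TPM in females and 22.4 ± 22.9 TPM in males, and vtg2 at 53860 ± 125 against 10.3 ± 9.84 TPM (SD, n = 3 each). The estrogen receptor gene esr1 was at 25.0 ± 3.23 TPM in control females and 0.447 ± 0.224 TPM in control males, a log2 difference of 4.17 ± 0.23 (SE, adjusted p = 3.84e-07).

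**Figure D2:**
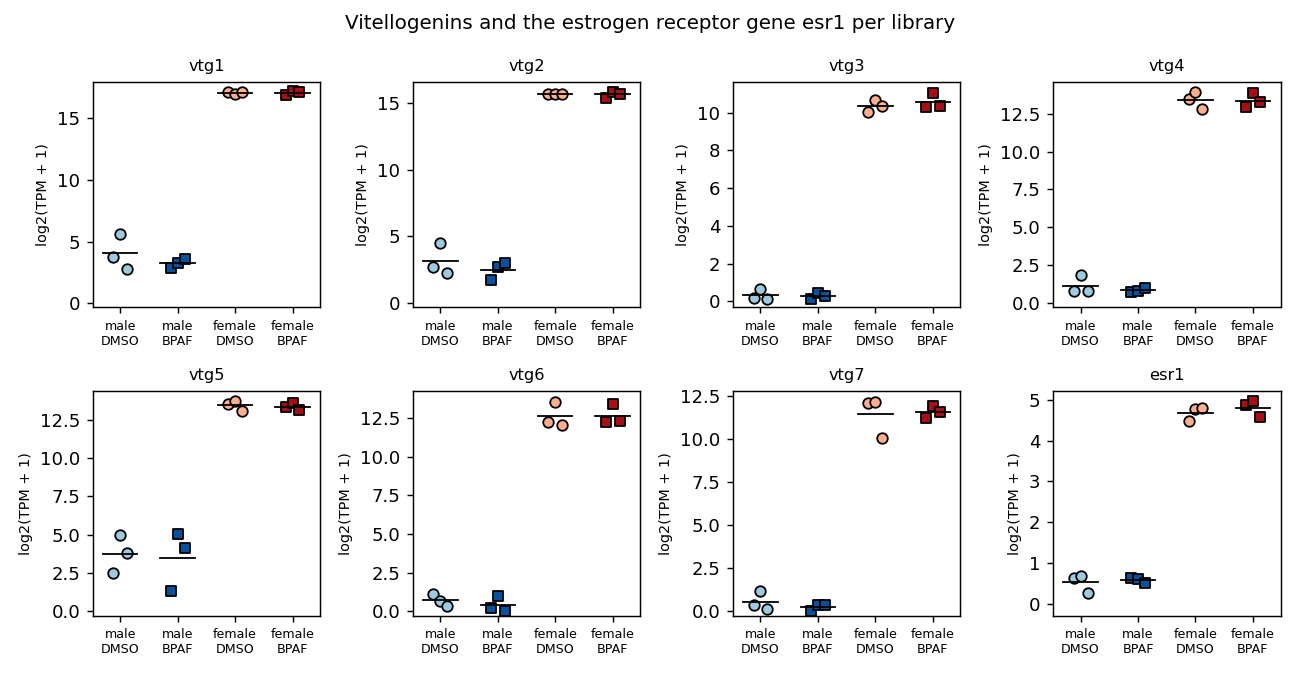
Expression of vtg1 to vtg7 and esr1 as log2(TPM + 1) in each library, with points for the 3 libraries of a group and a line at their mean. All 6 female libraries lie above all 6 male libraries in each panel, and BPAF libraries overlap the DMSO libraries of their sex.

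Besides the vitellogenins, the gene with the smallest p among those higher in control females than in control males was fam20cl, listed at 0 in all male libraries and at 171 ± 16.4 TPM in control females. The cytochrome P450 gene cyp2k6 was also higher (113 ± 5.54 against 0.167 ± 0.139 TPM), as was nots (1476 ± 595 against 0.890 ± 0.451 TPM, SD, n = 3 each). Their adjusted p-values were 1.84e-09, 1.32e-08 and 1.64e-08. Lower in females were cyp2k22 (0.163 ± 0.142 against 231 ± 126 TPM), the amino acid transporter gene slc38a3a (0.0467 ± 0.0462 against 6.50 ± 1.62), the nucleoside diphosphate kinase gene nme4 (54.9 ± 8.15 against 295 ± 28.6), the apolipoprotein gene apom (641 ± 142 against 2760 ± 144) and EIF3J (0.153 ± 0.266 against 6.67 ± 1.36), with adjusted p between 6.82e-06 and 0.000333. Of the panel, the fatty acid desaturase gene scd was higher in control females (43 ± 17.5 against 1.37 ± 2.09 TPM, adjusted p = 0.00943), and cyp3a65 (22.5 ± 9.41 against 153 ± 46.9 TPM, adjusted p = 0.0026) and the hepatocyte fatty acid binding protein gene fabp10a (20930 ± 1150 against 66310 ± 10730 TPM, adjusted p = 0.00636) were lower. The fabp10a call was lost with trimmed-mean scaling (adjusted p = 0.224) and with quantile normalization (0.0755). The panel genes pck1, hmgcra, cpt1aa, cyp7a1, fasn, igf1, cyp1a, hamp and hspa5 did not pass between control females and control males, with adjusted p from 0.0574 for hmgcra to 0.894 for cyp7a1. Of these, hmgcra, the rate-limiting enzyme gene of cholesterol synthesis, passed as higher in females with trimmed-mean scaling (adjusted p = 0.0299), with quantile normalization (0.0325) and with the replicate block (0.0491), and without male BPAF 1 (0.0181) or male BPAF 2 (0.0345). It also passed with the filter at 5 TPM (0.0347), a pseudocount of 0.1 (0.0463), only the DMSO libraries (0.0139) and array quality weights (0.0381). As lower in females, hamp passed with the block (0.0339) and without male DMSO 2 (0.0377), and igf1 without male DMSO 3 (0.0314).

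In all, 2655 of 11389 genes passed between control females and control males, 239 higher and 2416 lower in females, and 6762 passed with the sexes averaged over treatment, 449 higher and 6313 lower. The split depended on the scaling. The median log2 difference of all tested genes was -0.52, and it moved to -0.03 with trimmed-mean scaling and to -0.01 with quantile normalization. The control contrast then gave 542 higher and 484 lower genes with the former and 488 higher and 402 lower with the latter. The averaged contrast gave 1561 higher and 1545 lower with trimmed means and 1585 higher and 1441 lower with quantiles. Without female DMSO 1 the control count was 909, without male DMSO 1 it was 1277, without male DMSO 2 it was 1447 and without female DMSO 3 it was 1591.

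Ribosomal protein genes and estrogen-responsive genes were higher in control females under every scaling. In the estrogen response list, 9 of 10 tested members were higher and 0 lower, with the same count adjusted over the list alone (camera adjusted p = 8.1e-43, and adjusted p = 0.00467 with an estimated correlation). Of 77 tested ribosomal protein genes, 60 were higher and 1 lower (65 and 1 adjusted over the list alone). The counts were 67 higher and 0 lower with trimmed-mean scaling and 41 higher and 0 lower with quantile normalization. The ribosomal list had a camera adjusted p of 8.86e-64, and an adjusted p = 0.0977 with an estimated correlation, which was 0.0376 in the contrast averaged over treatment. For example, rpl34 stood at 7312 ± 493 TPM in control females and 3074 ± 54.4 TPM in control males, and rpl35 at 4621 ± 774 and 1485 ± 149 TPM (SD, n = 3 each). Hepatocyte markers were lower in 13 of 17 (14 over the list alone), a number that was 3 with trimmed-mean scaling and 9 with quantile normalization (camera adjusted p = 0.000117, adjusted p = 0.463 with an estimated correlation). Ovary and germline markers were higher in 6 of 22 and in 18 adjusted over the list alone, where 4 of 22 were higher with trimmed-mean scaling and 2 with quantile normalization (camera adjusted p = 3.26e-19, adjusted p = 0.463 with an estimated correlation). Genes of xenobiotic metabolism phase 1 did not pass as a list, with 1 of 32 higher and 8 lower (camera adjusted p = 0.748), counts that were 4 and 3 under either scaling. Conjugation enzymes were lower in 21 of 40, a number that was 5 under either scaling (camera adjusted p = 0.0216, adjusted p = 0.651 with an estimated correlation). The list tests between the sexes were added after the gene counts were known. Of 43 lists, 18 passed with the preset correlation and 1 with an estimated one. With fry, which does not compare a list with the other genes, 28 passed.

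BPAF exposure in males was followed by a change in 6 genes, 5 of them at a few TPM. CR788316.1 (ENSDARG00000105731) rose from 0.440 ± 0.415 to 6.11 ± 0.397 TPM and si:dkey-26m3.3 (ENSDARG00000101695) from 0.533 ± 0.251 to 4.24 ± 1.35 TPM (SD, n = 3 each). The gene si:ch211-261n11.7 (ENSDARG00000068966), named tnfrsf14 in the gene name table, rose from 0.310 ± 0.173 to 3.65 ± 0.568 TPM, and si:ch211-160o17.3 (ENSDARG00000105387) from 0.0400 ± 0.0693 to 1.37 ± 0.215 TPM. The gene si:ch73-167f10.1 (ENSDARG00000102946) was listed at 0 in all control males and at 3.25, 2.49 and 1.5 TPM in the exposed males. The 1 gene that fell was FO704772.1 (ENSDARG00000111902), a copy of the 5.8S ribosomal RNA gene, at 122.72, 771.79 and 6079.65 TPM in the control males and listed at 0 in all 3 exposed males.

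**Figure D3:**
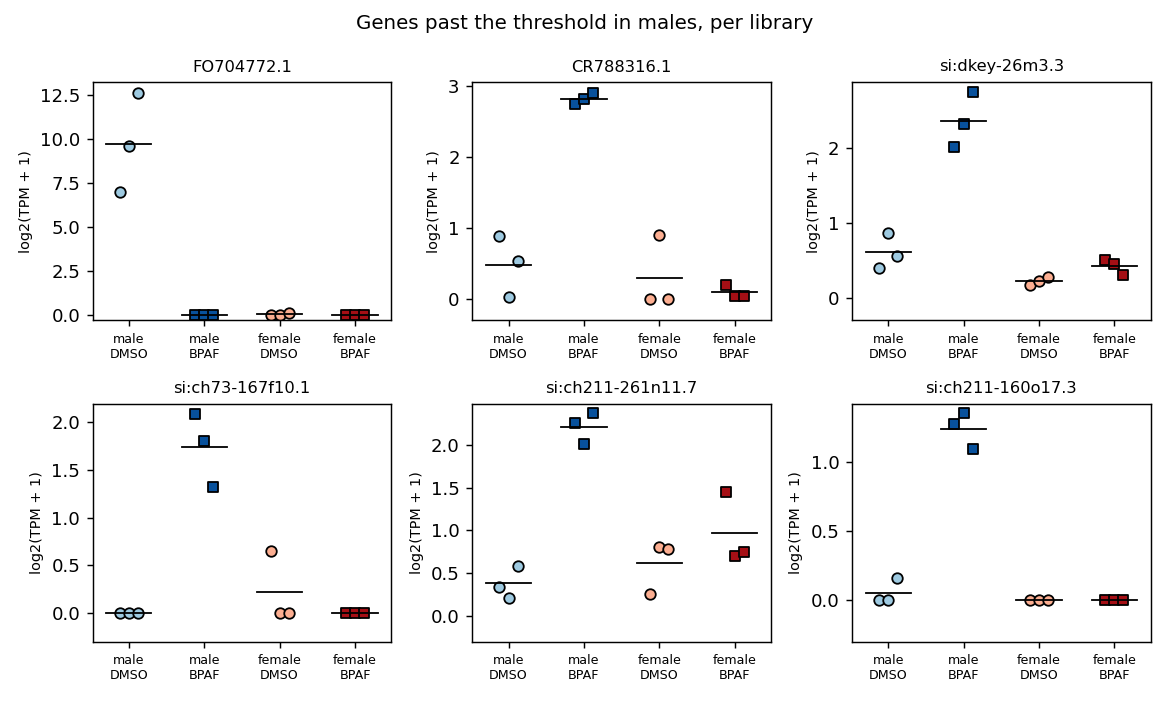
Expression of the 6 genes that passed in males, as log2(TPM + 1) in each library, with points for the 3 libraries of a group and a line at their mean. In males the DMSO and BPAF points do not overlap in any panel, and the female libraries lie at or below 0.86 TPM in all panels except that of si:ch211-261n11.7, where they reach 1.74 TPM.

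The log2 fold changes were 2.34 ± 0.28 for CR788316.1, 1.83 ± 0.26 for si:ch211-261n11.7, 1.75 ± 0.23 for si:dkey-26m3.3 and 1.18 ± 0.17 for si:ch211-160o17.3 (SE). The limma adjusted p was 0.00463 for FO704772.1, 0.0185 for CR788316.1, 0.0226 for si:dkey-26m3.3 and 0.0325 for the other 3. The spread behind these p-values is pooled over all 4 groups, which can understate the spread among males. For FO704772.1 all female libraries were at 0 or 0.07 TPM, while the control males ranged from 122.72 to 6079.65 TPM. With only the male libraries, a fit with fewer residual degrees of freedom, the limma adjusted p of the 6 genes was 0.199 to 0.413. At an unadjusted p under 0.05 there were 722 genes, 672 higher and 50 lower, and 1170 genes (10.3%) did not overlap between exposed and control males, 1106 of them higher and 64 lower in exposed males, where chance gives 10% in all. The count rested on the processing: it was 1 with trimmed-mean scaling, with quantile normalization, with a pseudocount of 0.1 and with the replicate number as a block, and 2 with the block within each sex. It was 0 with only the male libraries, without male DMSO 1 and without male DMSO 2, 2 without male DMSO 3 (0 of them among the 6), 1 without male BPAF 1, 2 without male BPAF 2 and 3 without male BPAF 3. Without an exposed male, 4 of the 6 genes (all but si:ch211-261n11.7 and FO704772.1) fell below the expression filter and were not tested, and neither was FO704772.1 without a control male. It was also 2 without female DMSO 2 or female DMSO 3 and 1 without female BPAF 2 or female BPAF 3, and 10 with a pseudocount of 5 and 73 with no filter. The gene that still passed under trimmed-mean scaling was FO704772.1 (adjusted p = 0.0229), as it did with the block over all libraries (0.0189).

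Among genes with a descriptive symbol, none passed in males. Those with the smallest p on the higher side were gstp2, a glutathione S-transferase (0.0267 ± 0.0462 to 1.23 ± 0.284 TPM, adjusted p = 0.0658), cfap299 (0.257 ± 0.394 to 2.19 ± 0.59, 0.112), nmrk2, for a nicotinamide riboside kinase (2.69 ± 2.37 to 35.5 ± 4.71, 0.211), myhb (0.147 ± 0.124 to 1.22 ± 0.307, 0.211) and the transcription factor gene mafa (0.68 ± 0.284 to 3.04 ± 0.38, 0.219). On the lower side, soga3a (1.73 ± 1.09 TPM in controls) and tspan9a (2.11 ± 1.03 TPM) were listed at 0 in all exposed males, with adjusted p of 0.126 and 0.283. EIF3J stood at 6.67 ± 1.36 and 2.33 ± 0.418 TPM, crabp1a, for a retinoic acid binding protein, at 5.8 ± 4.96 and 0.193 ± 0.335, and dio3b, for a thyroid hormone deiodinase, at 6.32 ± 2.97 and 2.61 ± 1.14 TPM in control and exposed males (adjusted p = 0.422, 0.483 and 0.665). The markers of testis had mean log2 levels of 1.09, 1.07 and 0.605 in the exposed males and 0.373 ± 0.0358 in the control males (SD, n = 3, exact permutation p = 0.1, the smallest that 20 splits allow).

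None of the 20 panel genes passed in males. Exposed males had 8.69 ± 2.26 TPM of vtg1 against 22.4 ± 22.9 in control males, 5.06 ± 2.44 against 10.3 ± 9.84 of vtg2, and 16.6 ± 15 against 16.0 ± 13.4 of vtg5. They had 0.497 ± 0.0681 TPM of esr1 against 0.447 ± 0.224 (SD, n = 3 each). Log2 differences of vtg3, vtg4, vtg6 and vtg7 lay between -0.33 and -0.04. The metabolic genes showed log2 differences of 1.23 ± 0.74 for hmgcra, 0.90 ± 0.97 for scd, 0.78 ± 0.50 for igf1, 0.65 ± 0.43 for cyp3a65, 0.62 ± 0.42 for cpt1aa, 0.37 ± 0.88 for pck1 and -1.0 ± 0.98 for fasn (SE). Those of cyp1a, fabp10a, hamp, cyp7a1 and hspa5 were 0.15 ± 0.33, 0.15 ± 0.32, 0.08 ± 0.99, -0.01 ± 1.13 and -0.54 ± 1.22. The adjusted p-values of the panel in males were 0.792 or more.

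The median log2 change of all tested genes in males was 0.24, and it moved to -0.02 with trimmed-mean scaling and to -0.01 with quantile normalization, so the lists are described relative to the other genes. With the preset correlation, 12 of 43 lists passed in males, 3 higher and 9 lower than the other genes. None passed with an estimated correlation (smallest adjusted p = 0.89) or with fry (0.434). Markers of intestine were higher, with a positive log2 change in 14 of 14 members and a median of 1.37 (camera adjusted p = 0.000308, 0.999 with an estimated correlation). The protease gene mep1b stood at 2.66 ± 4.14 TPM in control and 13.9 ± 5.42 TPM in exposed males, agr2 at 1.44 ± 0.972 and 5.44 ± 3.71, and the peptide transporter gene slc15a1b at 0.687 ± 0.918 and 6.14 ± 4.79. The mean log2 level of the intestine markers was 4.02 ± 1.35 in exposed and 2.74 ± 1.12 in control males (SD, n = 3 each, exact permutation p = 0.3). It was higher in the exposed male of all 3 same-numbered pairs, by 1.04, 1.21 and 1.59 (exact paired permutation p = 0.25, the smallest that 8 sign changes allow). Members of the p53 and apoptosis list were positive in 26 of 26 (median 0.46, adjusted p = 0.00928) and those of the interferon list in 28 of 29 (median 0.55, adjusted p = 0.0108), both with adjusted p = 0.999 with an estimated correlation. These signs are counted against 0, while the median of all tested genes was 0.24. With trimmed-mean scaling the p53 and interferon medians were 0.19 and 0.24, against -0.02 for all genes. With quantile normalization they were 0.201 and 0.325, against -0.01 for all genes. In these lists gadd45ab, a stress response gene, stood at 0.93 ± 0.481 and 3.38 ± 2.2 TPM, bik at 2.18 ± 0.657 and 5.37 ± 1.22, b2ml at 48.0 ± 5.35 and 79.3 ± 7.51 and the interferon regulatory factor gene irf1b at 7.65 ± 3.53 and 18.4 ± 6.05 TPM in control and exposed males.

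Exocrine pancreas markers were lower in exposed males, with 21 of 24 negative and a median of -0.64 (camera adjusted p = 1.2e-13, 0.89 with an estimated correlation). Their mean log2 level differed by 0.191, -1.25 and -0.218 in the same-numbered pairs, so it was higher in the exposed male of 1 pair (exact paired permutation p = 0.5). Examples were sycn.2 at 11.8 ± 7.48 and 4.78 ± 2.72 TPM and the elastase gene ela3l at 31.6 ± 15.9 and 18 ± 12.9 TPM in control and exposed males. The estrogen response list had 9 of 10 members negative and a median of -0.30 (adjusted p = 9.46e-05), and hepatocyte markers had 9 of 17 negative and a median of -0.05, which was 0 and no longer below all genes with quantile normalization (adjusted p = 0.00485), both with adjusted p = 0.89 with an estimated correlation. Ovary and germline markers (20 of 22 negative, median -0.45, adjusted p = 9.46e-05) and erythrocyte markers (10 of 14 negative, median -0.10, adjusted p = 0.00139) had adjusted p = 0.999 with an estimated correlation. In the ovary and germline list, ddx4 and dazl went the other way, at 0.0833 ± 0.085 and 1.39 ± 0.847 TPM and at 0.207 ± 0.183 and 1.34 ± 0.83 TPM. The lists of ribosomal proteins, the endoplasmic reticulum stress response, oxidative phosphorylation and the acute phase and complement were lower than other genes by the test (adjusted p = 0.00594, 0.00647, 0.0152 and 0.0176, each 0.999 with an estimated correlation), while their medians (0.04, 0.00, 0.10 and 0.13) and means were at or above 0. With trimmed-mean scaling these medians were -0.30, -0.25, -0.24 and -0.20, against -0.02 for all genes. With quantile normalization they were 0.10, -0.17, -0.08 and -0.03, against -0.01 for all genes, so the direction of ribosomal proteins turned. Adjusted over the list alone, 2 genes passed in males, both higher: gstp2 among conjugation enzymes (0.00162) and the immunoglobulin light chain gene igl1c3 among lymphocyte markers (0.00327).

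Of the 12 male list calls, that of exocrine pancreas held with each of the 12 libraries left out in turn. The intestine call was lost without male DMSO 2 (adjusted p = 0.109) and male BPAF 3 (0.497), and the interferon call without male DMSO 1 (0.496), male DMSO 3 (0.0615) and male BPAF 2 (0.515). The p53 call was lost without male DMSO 1 (0.0511), male DMSO 2 (0.0896) and male BPAF 1 (0.0665), and the estrogen response call without male DMSO 2 (0.109) and male BPAF 1 (0.234). Ovary and germline markers lost their call without male DMSO 3 (0.52) and with trimmed-mean scaling (0.352), erythrocyte markers without male DMSO 1 (0.243), and hepatocyte markers without male DMSO 1 (0.0511) and male BPAF 1 (0.25). The ribosomal call was lost without male DMSO 2 (0.134), male DMSO 3 (0.85), male BPAF 1 (0.987) and male BPAF 2 (0.723). The endoplasmic reticulum stress call was lost without male DMSO 1 (0.165), male DMSO 3 (0.446), male BPAF 2 (0.515) and male BPAF 3 (0.545). Oxidative phosphorylation was lost without male DMSO 1 (0.0902), male DMSO 3 (0.52), male BPAF 1 (0.233) and male BPAF 2 (0.299), and the acute phase without male DMSO 1 (0.437), male DMSO 3 (0.0615) and male BPAF 3 (0.772).

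In exposed females, genes of amino acid breakdown, the circadian clock and cholesterol synthesis were lower as groups than other genes with a preset correlation and not with an estimated one (smallest adjusted p = 0.635). Their median log2 changes were -0.34, -0.42 and -0.45. BPAF exposure in females left 0 genes past the threshold in limma, with 157 genes at an unadjusted p under 0.05 (67 higher, 90 lower) and a smallest adjusted p of 0.869. Exposed and control females did not overlap in 510 genes (4.48%), 268 higher and 242 lower in exposed females, where chance gives 10%. The vitellogenins did not pass: vtg1 was at 137300 ± 13590 TPM in exposed and 137900 ± 11410 TPM in control females, vtg2 at 52540 ± 8287 and 53860 ± 125, and esr1 at 27.4 ± 3.92 and 25.0 ± 3.23 (SD, n = 3 each). The genes with the smallest p on the higher side, none of which passed, were GGT7 (0.0667 ± 0.0289 to 1.65 ± 0.6 TPM), znf1096 (0.183 ± 0.0808 to 2.06 ± 0.771), smpdl3a, for a phosphodiesterase of the sphingomyelinase family (0.853 ± 0.287 to 13.5 ± 8.6), rnf25 (5.15 ± 0.554 to 16.6 ± 9.48) and the germ cell gene dnd1 (1.85 ± 2.21 to 9 ± 0.639). On the lower side were the myosin gene myo3b (29.4 ± 5.15 to 2.32 ± 2.68 TPM, adjusted p = 0.869), the cell adhesion gene ncam1a (7.20 ± 3.09 to 1.21 ± 0.753), hist1h4l (2.34 ± 0.756 to 0.167 ± 0.289), the sulfotransferase gene sult1st1 (5.44 ± 3.4 to 0.850 ± 0.36) and alkbh5 (5.32 ± 1.41 to 2.58 ± 0.478).

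None of the 20 panel genes passed in females (adjusted p = 1 for each). The gluconeogenesis gene pck1 stood at 34.4 ± 13.8 TPM in control and 11.8 ± 12.6 in exposed females, scd at 43 ± 17.5 and 12 ± 8.51, cyp1a at 100.3 ± 34.1 and 62.2 ± 10.2, and the hepcidin gene hamp at 71.6 ± 70.4 and 41.1 ± 42.2 TPM (SD, n = 3 each). Log2 differences were -0.68 ± 0.98 for fasn, -0.49 ± 1.13 for cyp7a1, -0.47 ± 0.74 for hmgcra, -0.19 ± 0.43 for cyp3a65, 0.36 ± 0.43 for cpt1aa and 0.26 ± 0.32 for fabp10a (SE). Those of igf1, hspa5, vtg3, vtg4, vtg5, vtg6 and vtg7 lay between -0.10 and 0.22.

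Lists of metabolic and clock genes were lower than other genes in exposed females with the preset correlation. In all, 9 of 43 lists passed, 8 lower and 1 higher. None passed with an estimated correlation (smallest adjusted p = 0.635) or with fry (0.992), and 0 members passed when adjusted over the list alone. The amino acid catabolism list had 30 of 33 members negative (median -0.34, adjusted p = 8.93e-11, 0.635 with an estimated correlation). The phenylalanine hydroxylase gene pah stood at 128 ± 22.2 and 64.6 ± 10.4 TPM and mat1a at 185 ± 45.2 and 121 ± 14.1 TPM in control and exposed females. The circadian clock list had 22 of 27 negative (median -0.42, adjusted p = 3.63e-10, 0.635 with an estimated correlation). Its member cry2 stood at 5.17 ± 1.97 and 2.24 ± 0.205, per1b at 5.4 ± 1.73 and 2.6 ± 0.56 and nr1d1 at 9.83 ± 1.92 and 4.67 ± 3.43 TPM. All 22 tested genes of cholesterol synthesis were negative (median -0.45, adjusted p = 4.77e-08, 0.636 with an estimated correlation). Of these, insig1 stood at 26.8 ± 20.6 and 8.67 ± 1.36 and msmo1 at 17.1 ± 3.48 and 8.74 ± 2.77 TPM. Glucose metabolism had 20 of 25 negative (median -0.16, adjusted p = 0.000535, 0.636 with an estimated correlation). Here gpia stood at 80.1 ± 13.9 and 49.8 ± 8.18 and pck2 at 71.3 ± 11.9 and 48.0 ± 1.01 TPM. These 4 lists kept their direction under both scalings, and the first 3 passed with each library left out, while glucose metabolism did not without female DMSO 3 (adjusted p = 0.0724).

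The other lists that were lower in exposed females had an adjusted p = 0.954 with an estimated correlation. Oxidative phosphorylation had 50 of 60 members negative (median -0.16, adjusted p = 0.000535), ovary and germline markers 21 of 22 (median -0.86, adjusted p = 0.000626), inflammation 18 of 25 (median -0.15, adjusted p = 0.0203) and cell cycle 28 of 32 (median -0.23, adjusted p = 0.0203). In the inflammation list the immediate early genes egr1 (10.0 ± 5.8 and 2.15 ± 1.92 TPM) and junba (24.1 ± 16.2 and 6.81 ± 7.46 TPM) were among the members with the smallest p, and the chemokine gene ccl34a.4 went the other way (1.69 ± 1.2 and 10.8 ± 11.4 TPM). Ribosomal proteins were higher, with 49 of 77 positive and a median of 0.05 (adjusted p = 0.0324, 0.954 with an estimated correlation), which was 0.00815 against 0.00568 for all genes with quantile normalization. The cell cycle and ovary lists turned direction without female DMSO 1 (adjusted p = 0.293 and 0.795) and without female BPAF 2 (0.789 and 0.706), and cell cycle was also lost without female BPAF 3 (0.461). Oxidative phosphorylation turned without female DMSO 2 (0.927) and was lost without female BPAF 1 (0.189) and female BPAF 2 (0.346). Inflammation was lost without female DMSO 3 (0.838), female BPAF 2 (0.0988) and female BPAF 3 (0.372) and with the block within each sex (0.0646). The ribosomal call was lost without female DMSO 2 (0.385), female DMSO 3 (0.13), female BPAF 2 (0.672), female BPAF 3 (0.944, direction turned) or male BPAF 1 (0.0506). The mean log2 level of ovary markers was 3.59, 2.52 and 1.31 in the control and 3.85, 0.458 and 1.41 in the exposed female libraries.

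In the interaction, the lists with the smallest adjusted p by the test with a preset correlation were exocrine pancreas markers and genes of cholesterol synthesis. The former had a median log2 change of -0.64 in males and 0.14 in females, and the latter 0.41 and -0.45, with an adjusted p of 0.99 with an estimated correlation for both. The mean level of the pancreas markers overlapped between exposed and control libraries of each sex (exact permutation p = 0.4 in males and 0.9 in females). In same-numbered males, this level changed unevenly, by 0.191, -1.25 and -0.218 (exact paired permutation p = 0.5). Tested gene by gene, 0 genes passed in limma, with 368 at an unadjusted p under 0.05 (46 higher and 322 lower in the female response) and a smallest adjusted p of 0.163. The genes with the smallest p, none of which passed, included ncam1a, whose log2 change was 1.22 in males and -1.88 in females (interaction -3.10 ± 0.57, SE, adjusted p = 0.499). The interaction was also negative for the kinase gene ttk (-1.48 ± 0.34) and for sult1st1 (-2.30 ± 0.57), and gstp2, listed at 0 in all control females, and cfap299, listed at 0 in all female libraries, were among these genes too, each with an adjusted p of 0.995. On the higher side were EIF3J (1.95 ± 0.41, adjusted p = 0.768), smpdl3a (4.03 ± 0.87, 0.768), the nuclear receptor gene roraa (4.52 ± 1.3, 0.995), crabp1a (2.65 ± 0.84, 0.995) and soga3a (0.995), the last of which was listed at 0 in all libraries except the control males. For roraa, the levels were 228 ± 242 and 61.7 ± 66.1 TPM in control and exposed males and 8.63 ± 2.96 and 67.8 ± 37.7 TPM in control and exposed females (SD, n = 3 each). None of the 20 panel genes passed in the interaction, where scd had -2.95 ± 1.36 and pck1 -2.52 ± 1.24.

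Of the 43 lists, 13 passed in the interaction with the preset correlation, 7 higher and 6 lower in the female response than other genes. Since hepatocyte markers share members with other lists, the 13 lists are not all separate findings. None passed with an estimated correlation (adjusted p = 0.99 for each) or with fry (smallest 0.743). The median interaction of all tested genes was -0.25, which moved to 0.02 with trimmed-mean scaling and to 0.01 with quantile normalization. Cholesterol synthesis had all 22 members negative, with a median log2 change of 0.41 in males and -0.45 in females (interaction median -0.82, adjusted p = 4.73e-05, 0.99 with an estimated correlation). The signs are counted against 0. Its interaction median was -0.57 with trimmed-mean scaling and -0.534 with quantile normalization, against 0.02 and 0.01 for all genes. Its member sc5d stood at 0.96 ± 0.624 and 2.37 ± 0.85 TPM in control and exposed males and 1.78 ± 0.789 and 0.850 ± 0.738 TPM in control and exposed females. Exocrine pancreas markers had 23 of 24 members positive (medians -0.64 in males and 0.14 in females, adjusted p = 9.04e-11, 0.99 with an estimated correlation). Both calls held with each library left out. The other 11 lists lost their call without at least 1 library, and the number of all lists that passed fell from 13 to 8 without male DMSO 1 or male BPAF 2 and to 6 without male BPAF 3. Adjusted over the list alone, 3 genes passed, all lower in the female response: sult1st1 and gstp2 among conjugation enzymes (0.0361 each) and igl1c3 among lymphocyte markers (0.04).

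**Figure D4:**
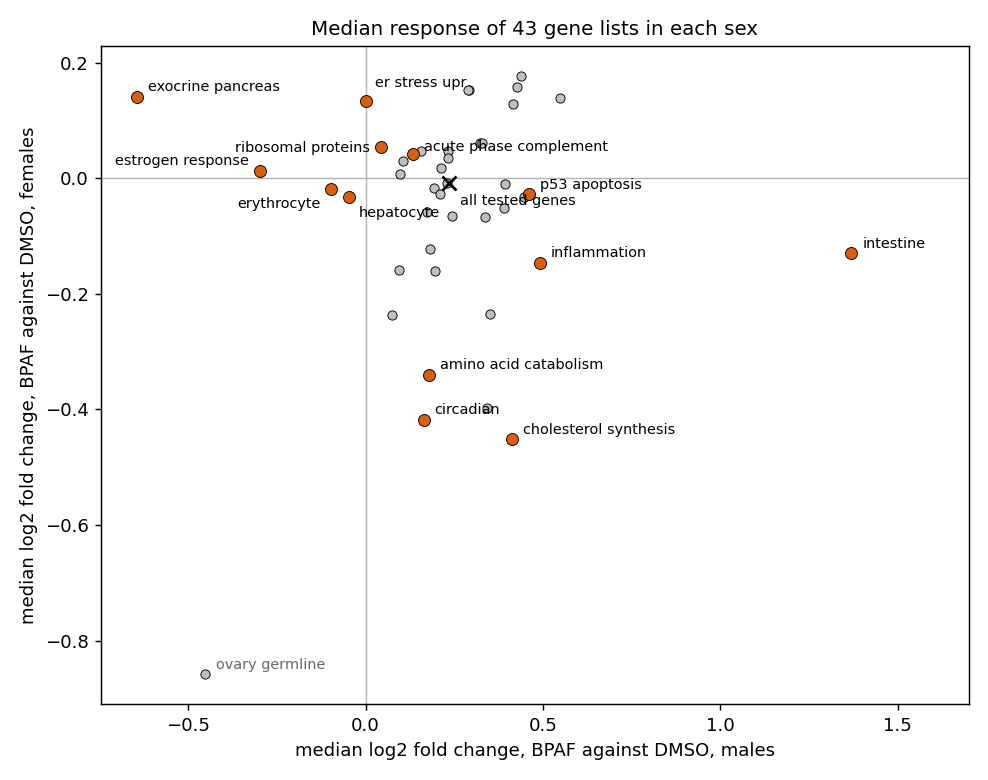
Median log2 fold change of BPAF against DMSO for 43 gene lists in males (horizontal) and females (vertical), with orange points for the 13 lists that passed in the interaction with a preset correlation and grey points for the others. The cross marks the median of all tested genes (0.24 in males, -0.01 in females), and none of the lists passed with an estimated correlation.

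Across genes, the responses of males and females were close to uncorrelated. Log2 changes of the 11389 genes correlated at r = -0.0115 (Spearman rho = 0.0415, covariance -0.00189), and 49.0% of genes had the same sign. Genes are not independent replicates. The contrasts share no library, but they use the same variance estimate for each gene. A gene with a low estimate tends to a small p in both sexes, so the counts for independent lists are too low a reference. No gene passed in both sexes. At an unadjusted p under 0.05, 6 genes were higher in both sexes (3.95 for independent lists), among them galnt18b (log2 changes of 1.93 in males and 2.37 in females) and GGT7 (1 and 1.29), and 3 were lower in both (0.395 for independent lists), among them camta1b (-1.28 and -1.92). In opposite directions, 5 were higher in males and lower in females (5.31 for independent lists), among them the apolipoprotein gene apoa4a (1.5 and -1.32), and 3 the reverse (0.294 for independent lists), among them EIF3J (-1.20 and 0.75).

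Genes with a sex difference were asked as sets whether exposure moved them. The 449 genes higher in females had a median log2 change of 0.00 in exposed males, where all tested genes had 0.24 (camera adjusted p = 7.83e-08, 0.472 with an estimated correlation), and -0.07 in exposed females (adjusted p = 0.0571, 0.845 with an estimated correlation). Genes near 0 TPM in males change little on the log2(TPM + 1) scale, and how many of the 449 were so was not counted. The lag of this set behind all genes in males is therefore not by itself a response to BPAF. With the replicate block within each sex the set passed in females (adjusted p = 0.00148). With trimmed-mean scaling, which gives 1561 genes higher in females, the median in males was -0.03 and the set did not pass (adjusted p = 0.9). The 6313 genes higher in males had medians of 0.23 in exposed males and 0.00 in exposed females (adjusted p = 0.378 and 0.19).

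The lists of xenobiotic metabolism phase 1, antioxidant defence, lipogenesis, fatty acid oxidation, lipoprotein transport, bile acids, insulin and growth factor signalling, heat shock, the tricarboxylic acid cycle, the proteasome, lysosome and autophagy, steroid metabolism, thyroid, hypoxia, iron and metals, and matrix did not pass in males, in females or in the interaction. Neither did the conjugation enzymes nor the markers of cholangiocytes, endocrine pancreas, macrophages, neutrophils, lymphocytes, endothelium, stellate cells and adipocytes. The smallest camera adjusted p among lists that did not pass was 0.0539 in males (thyroid), 0.0625 in females (endoplasmic reticulum stress) and 0.0605 in the interaction (glucose metabolism).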

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

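The interaction tests of lists and genes given here were chosen before the results were seen, while the trimmed-mean scaling and the block within each sex were added afterwards. In 13 lists the female minus male response differed from that of other genes with a preset correlation, and each had an adjusted p of 0.99 with an estimated correlation.

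Exocrine pancreas markers had the lowest adjusted p (9.04e-11), with medians of -0.64 in males and 0.14 in females, and cholesterol synthesis (4.73e-05) had medians of 0.41 in males and -0.45 in females. Both lists passed with each of the 12 libraries left out. With quantile normalization the interaction medians of ribosomal proteins (-0.09), the acute phase list (-0.06) and hepatocyte markers (-0.16) lay below that of all genes (0.01), opposite to the tests given here. Ribosomal proteins (0.000243) had medians of 0.04 in males and 0.05 in females. Their interaction median of -0.01 was negative but above the median of all genes (-0.25), to which the test (higher) refers. That call was lost without male DMSO 3 (0.201), male BPAF 1 (0.275), male BPAF 2 (0.151) and female BPAF 3 (0.0533). The endoplasmic reticulum stress list (0.000416) had medians of 0.00 in males and 0.13 in females and was lost without male DMSO 3 (0.0585), male BPAF 2 (0.0893) and male BPAF 3 (0.0941).

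The estrogen response list (0.000703) had medians of -0.30 in males and 0.01 in females and was lost without male DMSO 2 (0.0937), male BPAF 1 (0.275) and female DMSO 3 (0.0562). Amino acid catabolism (0.00385) had medians of 0.18 in males and -0.34 in females and was lost without male DMSO 3 (0.201), male BPAF 2 (0.0951) and male BPAF 3 (0.195). The p53 and apoptosis list (0.00396) had medians of 0.46 in males and -0.03 in females and was lost without female DMSO 3 (0.058). Intestine markers (0.00559) had medians of 1.37 in males and -0.13 in females and were lost without male DMSO 1 (0.0782), male DMSO 2 (0.202), male BPAF 3 (0.546) and female DMSO 2 (0.102).

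Erythrocyte markers (0.015) had medians of -0.10 in males and -0.02 in females and were lost without male DMSO 1 (0.276), male BPAF 2 (0.058), male BPAF 3 (0.128) and female DMSO 3 (0.152). The acute phase and complement list (0.0186) had medians of 0.13 in males and 0.04 in females. Its interaction median of -0.15 and mean of 0.00 lay above the median of all genes (-0.25), to which the test (higher) refers. It was lost without male DMSO 1 (0.276), male BPAF 3 (0.464), female DMSO 1 (0.154), female DMSO 2 (0.102) and female BPAF 1 (0.214), and with the replicate block within each sex (0.0521).

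The circadian clock list (0.0237) had medians of 0.16 in males and -0.42 in females. It was lost without male DMSO 3 (0.291), male BPAF 2 (0.151), male BPAF 3 (0.279), female DMSO 3 (0.676) and female BPAF 1 (0.126), and with the block within each sex (0.0521). The inflammation list (0.0369) had medians of 0.49 in males and -0.15 in females. It was lost with the replicate block (0.0561), with the block within each sex (0.102) and without male DMSO 1 (0.276), male DMSO 2 (0.228), male BPAF 1 (0.275), female DMSO 3 (0.507), female BPAF 2 (0.0939) and female BPAF 3 (0.324). Hepatocyte markers (0.0469) had medians of -0.05 in males and -0.03 in females. Their interaction median of -0.05 and mean of -0.02 were negative but above the median of all genes (-0.25), to which the test (higher) refers. They were lost with the replicate block (0.0514), with the block within each sex (0.0521) and without male DMSO 1 (0.202), male DMSO 2 (0.0937), male BPAF 1 (0.472), male BPAF 3 (0.0941), female DMSO 1 (0.117), female DMSO 2 (0.0885) and female BPAF 1 (0.154).

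Among the named genes, 3 were higher in all exposed than in all control males and lower in all exposed than in all control females. They had been named for a small p in these data, which favours such a separation. Over all tested genes, 10.3% did not overlap in males and 4.48% in females, where chance gives 10%. The interaction was -3.10 on the log2 scale for ncam1a (1.22 in males and -1.88 in females, adjusted p = 0.499), -2.30 for sult1st1 (0.67 and -1.63, adjusted p = 0.995) and -1.49 for sesn1 (0.66 and -0.84, adjusted p = 0.995). None of these passed the limma interaction test.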

How the results depend on the processing

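Added after the data had been seen were the replicate block within each sex, the trimmed-mean scaling of lists and of sex-biased sets, the estimated correlation for those sets, and simulated draws with no change. The count of 6 genes in exposed males was 1 with trimmed-mean scaling, quantile normalization, a pseudocount of 0.1 and the replicate block, 2 with the filter at 5 TPM and with the block within each sex, and 0 with only the male libraries. It was 10 with a pseudocount of 5 and 73 with no filter, and 0 to 5 with single libraries left out, where some of the 6 genes fell below the filter and were not tested. The model without trend gave 5, and array weights and a log2 minimum of 1 gave 6. In exposed females 3 genes passed with no filter and 0 under each other alternative. In the interaction 12 passed with no filter, 1 with a pseudocount of 0.1 and 1 with a pseudocount of 5, and 0 to 1 without single libraries (1 without female BPAF 3). The cause of these changes was not tested.

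Between control females and control males, 2655 genes became 1026 with trimmed-mean scaling (707 of them shared), 890 with quantile normalization (592 shared) and 1639 with no filter, and 909 to 3199 without single libraries. The averaged contrast of 6762 genes became 3106 with trimmed-mean scaling, 3026 with quantile normalization, 3183 with the filter at 5 TPM, which tests fewer genes, and 3369 with a log2 minimum of 1, which can only lower the count. For the scalings the weighing stands among the other observations. For the rest the cause was not tested. The replicate block gave 3123 and 7144.

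The overlap of 0 genes between the sexes was 9 at an unadjusted p under 0.05. With sex-biased genes from the DMSO libraries, the male-higher set passed in males (median 0.115) and in females (0.0683), as did the female-higher set in females (-0.0389). These libraries both chose the genes and served as controls, so such shifts arise with no effect. Relative to all genes the 3 medians were -0.12, 0.0774 and -0.0299, and the central 95% of 100 simulated draws with no change ran from -0.271 to 0.0154, -0.0327 to 0.118 and -0.545 to 0.187. The female-higher set in males lay at -0.185, where the draws ran from -0.146 to 0.483. These draws leave out the pairing of the male libraries. With same-numbered males drawn together they ran from -0.132 to 0.00347 for the male-higher and -0.0696 to 0.204 for the female-higher set in males. With a log2 minimum of 1 the female-higher set passed in females too (-0.265), as it did with the block within each sex at its median of -0.0666. The female-higher set in males no longer passed with an estimated correlation (median 0) or with trimmed-mean scaling (-0.031). The cause was not tested.

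With an estimated correlation 0 lists passed in males, 0 in females and 0 in the interaction, and fry gave 0, 0 and 0. Direction by fry was opposite to camera in males for endoplasmic reticulum stress (0.895), acute phase (0.807), oxidative phosphorylation (0.783) and ribosomal proteins (0.774), and in the interaction for acute phase (0.935) and hepatocyte markers (0.997), since fry does not compare a list with other genes. In females, leaving out single libraries gave adjusted p of 1.53e-11 to 0.789 for cell cycle, 1.58e-10 to 0.927 for oxidative phosphorylation, 1.48e-17 to 0.795 for ovary markers and 4.07e-07 to 0.944 for ribosomal proteins, and turned each of these. Lists without single libraries numbered 8 to 13 in males, 7 to 13 in females and 6 to 14 in the interaction.

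Apart from the calls named here, in the report and among the lists above, the replicate block changed no list call from passing to not passing, and 13 lists passed in males with either block. Of the named genes' values under the alternatives, 42 of 1794 in males, 42 of 1473 in females, 34 of 1679 in the interaction and 12 of 614 between the sexes changed sign, none of them for a gene that passed. Calls were newly made in 8, 0, 1 and 12 of these values and lost in 71, 0, 0 and 2. Alternatives for counts were not run because the values are TPM, and the depth is unknown.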

Other observations

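The tests of explanations below were chosen only after the results were seen, and the splits of the samples were fixed before. The livers held transcripts of other tissues at levels that differed between libraries of a group. Ovary and germline markers, of which 0 of 22 reached 1 TPM in all control males, had mean log2 levels of 3.59, 2.52 and 1.31 in the control females and 3.85, 0.458 and 1.41 in the exposed females (exact permutation p = 0.8). In males the level was 1.23 in male DMSO 3 and at most 0.278 in the other 5 libraries. Testis markers were at 1.09, 1.07 and 0.605 in the exposed males and 0.339 to 0.41 in the control males (exact permutation p = 0.1, the smallest possible), and at 0.237 and 0.243 in exposed and control females (exact permutation p = 0.8). For example, the meiosis gene sycp3 stood at 2.84 TPM in male BPAF 1 and 0.99 TPM in male BPAF 3, and the sperm flagellum gene tekt1 at 2.91 and 0.96 TPM. Intestine markers, of which 4 of 14 reached 1 TPM in all control males, were at 2.6, 1.69 and 3.93 in the control males and 3.64, 2.90 and 5.52 in the exposed males, in the order of the replicate numbers, higher in the exposed male of all 3 same-numbered pairs. Exocrine pancreas markers, of which 20 of 24 reached 1 TPM in all control males, had mean levels of 2.55 ± 0.606 in exposed and 2.98 ± 0.74 in control males (SD, n = 3 each, exact permutation p = 0.4). The differences in the same-numbered pairs were 0.191, -1.25 and -0.218 (exact paired permutation p = 0.5).

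Other splits of the samples were fitted in the same way. The 10 splits of the 6 male libraries are too few for a share under 0.05: the real split called 6 genes, the highest other 5, and 1 split called as many as the real one. Of the 4 splits that part all 3 pairs of same-numbered males, the highest other called 2, and the 6 splits that part 1 pair called up to 5. The 10 splits of the females are too few as well: the real split called 0 genes, so 10 of 10 called as many, and the highest called 221. That split set female DMSO 1, female DMSO 2 and female BPAF 1, the 3 libraries with the highest ovary marker levels, against the rest, which points to a structure of the samples. In the interaction the real split called 0 genes and the highest other 115. With a real count of 0, all 100 of 100 splits call as many whatever the data, so this count says nothing about chance. The 10 splits of the control libraries by sex are too few (real 2655, highest other 1, 1 split as high), and chance was excluded for the averaged contrast (real 6762, highest other 3147, 1 of 100 splits as high).

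Most genes that differed between the sexes were lower in females, with a median log2 difference of -0.66 over all tested genes. The share of TPM taken by the vitellogenins may lower all other genes, but after rescaling without them the median was still -0.42 (-0.482 to -0.341 with single libraries left out), with 627 genes higher and 4025 lower, which argues against the vitellogenins as the whole cause. The share taken by the most abundant genes as a whole stays open: without the 500 most abundant genes, which held 88.5% of TPM in males and 94.3% in females, the median was -0.0814 (-0.112 to -0.029), with 1757 higher and 1874 lower. Without 100, 200 and 1000 genes it was -0.212, -0.0352 and -0.148, and the number of 500 was picked after these were seen. A difference between the sexes in how many genes the liver expresses stays open as untested.

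The 5 genes that rose in exposed males stood at a few TPM. All 5 calls ended with trimmed-mean scaling and with quantile normalization (limma adjusted p = 0.137 to 0.295 with the latter). The fold changes stayed positive, so the calls depended on the scaling and the direction did not. Whether a shift of all genes in these libraries is the reason stays open. All tested genes had a median log2 change of 0.24, so scaling could not bring genes called at 1.18 or more near 0. After trimmed-mean scaling the median log2 change of the 5 genes was 1.37 (0.856 to 1.90, SE 0.153 to 0.308) against 1.75 before. Their calls ended (adjusted p = 0.232 each) because each fold change fell relative to its SE (0.17 to 0.285 before). Testis tissue stays open: of 19 testis markers, 18 were under 1 TPM in all control males (all but gsdf), and the 14 of these not at 0 in male BPAF 3 had a median ratio of male BPAF 1 to male BPAF 3 of 3.23. Their range of 0.735 to 7.24, from levels of at most 0.99 TPM in male BPAF 3, overlapped that of 4 of the 5 genes (median 0.891, 0.532 to 1.26) and held the 2.17 of si:ch73-167f10.1. Intestinal tissue stays open, since 0 of the 5 genes reached the lowest exposed male in male DMSO 3, but this was the only control male with intestine markers above those of any exposed male, and its own pair, male BPAF 3, stood above it, and an effect of BPAF stays open as untested.

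The 5.8S ribosomal RNA copy FO704772.1 was at 0 in all exposed males. Ribosomal RNA that varies between libraries whatever their group is a candidate explanation, since the summed TPM of the 6 genes named 5.8S differed 68-fold among the control males, and 3 of the 9 other libraries lay above the lowest control male, female BPAF 1 among them at 4745.05 TPM. Reads shared among near-identical copies stay open, because 1 of the 3 exposed males reached the lowest control male in the sum (615.65 against 207.39 TPM), while the other two were at 0. Why this copy was at 0 in all 3 exposed males while another was at 615.65 TPM in male BPAF 3 cannot be told apart from how the authors assigned such reads, and an effect of BPAF stays open as untested.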
